A study of Rattus norvegicus with 6 samples.

How the data were processed

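Polyadenylated RNA of rat islets was sequenced as single-end libraries that do not keep the strand, per the labels' protocols. The 6 libraries fall into a P10 group (10-day-old) and an adult group (3-month-old, male), with 3 labelled biological replicates each, so p-values measure the spread between these replicates. The labels do not say whether a P10 replicate pools islets of several pups, so that spread may not be one between single animals. Per the submitters' processing notes, the tools were Bowtie2, TopHat2 2.0.10 and HTSeq on the rn5 build, with DESeq and edgeR also named without a role. The deposited values used here are raw read counts per gene symbol, 1 file for each library. Only reads with a unique alignment that fell in a single gene entered a gene's count, per the counter rows of the deposited files. Reads shared by near-identical copies (Ins1 and Ins2, globins, amylases, trypsins, the RT1 genes, ribosomal proteins) are therefore missing or unevenly divided. Reads of overlapping or antisense genes could not be told apart without strand. A deposited table of all libraries held the same counts with some gene names turned into dates, and was not used.

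The 5 counter rows of each file stayed out of library sizes and tests. Ambiguous reads made up between 0.319% and 0.474%, and alignments that were not unique between 15.1% and 27.7%, of gene counts and counters together. The counters for reads outside genes and for unaligned reads list 0 in every library, so those shares are unknown. Gene counts per library ran from 3307415 to 6477825. Of 17055 gene rows 13245 had a count in some library.

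Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 (total of 15), which left 10124. Library sizes were scaled by trimmed mean of M values (TMM) factors, and a quasi-likelihood model with the age group as the only term was fitted to all 6 libraries. The adjusted p is the Benjamini-Hochberg false discovery rate (FDR) over all tested genes, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are normalised by the TMM factors, and folds are those of the fitted model, adult over P10 for rises and P10 over adult for falls. The biological coefficient of variation was 23.7%. For a gene with no count in a group the fold was set against 3 counts over the group, and for 1 to 5 counts the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only.

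In total, 32 gene lists with 692 entries were fixed before the data were examined. Of the entries 642 had a row, 10 through an older symbol given with the list and 2 through a synonym in a RefSeq gene table of the GRCr8 assembly, used for names only. The sex-linked list had no member with a row and gave no result. For each list the members past the threshold were counted over all genes and adjusted over the list alone. The camera test of limma 3.58.1 (two-sided, preset correlation 0.01) compared each of 30 lists with at least 5 tested members to all other genes. Its p-values were adjusted over these lists.

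Named genes followed a rule fixed at the same time. It takes the 8 largest rises and falls among called genes with at least 5 CPM on average and no overlap between groups, 16 genes fixed whatever their result, and up to 3 examples per list. The examples are the 2 smallest p in the direction most members took and the 1 smallest p in the other. Genes named outside this rule are said to be so, and 3 genes that it takes are not reported here.

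Alternatives were relative log expression factors, library totals alone, factors without hormone and acinar genes, DESeq2 1.42.0, no filter, a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, a test against a 1.5-fold change, leaving out each library, and, for lists, camera with an estimated correlation and fry. Leaving out ribosomal RNA genes was added after seeing the data. By the sample titles, the replicate numbers 1 and 3 occur in both groups.

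The script was tested on simulated counts with the means and library sizes of the adult against P10 comparison. Among 9910 simulated genes it recovered 54% of 100 genes changed 2-fold and 80% of 100 changed 4-fold, with 8 false calls among 9721 unchanged genes. Of the genes changed 2-fold it recovered 15 of the 50 with lower expression and 39 of the 50 with higher expression. The simulated list was found, and none of 30 random lists was called. The simulated genes were drawn independently of each other, so list calls among correlated genes were not tested. Apart from the changed genes both groups had the same means, so a shift of the insulin share was not simulated. Single values of 3 against 3 libraries were compared by exact permutation, whose smallest p is 0.1.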

Results

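Messenger RNA was sequenced from whole islets of Langerhans, the endocrine cell clusters of the pancreas, of Sprague-Dawley rats at 2 ages. The P10 group held islets of 10-day-old pups, and the adult group islets of 3-month-old males, with 3 libraries labelled as biological replicates in each. The comparison addresses how islet mRNA levels change during postnatal maturation of the insulin-producing beta cells, the subject named in the title of the series. The reads assigned to genes numbered 6477825, 5350737 and 3554194 in P10 replicates 1, 3 and 4, and 3307415, 3481376 and 6280144 in adult replicates 1, 2 and 3. A floor of 3 counts in a library corresponded to between 0.407 and 1.0995 normalised CPM (counts scaled to a common library size), for counting error only. The 2 insulin genes took 31.4% ± 2.71 (SD, n = 3) of the gene counts at P10 and 48.7% ± 3.11 (SD, n = 3) in adults. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow.

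Adult islets had higher mRNA levels of both insulin genes than P10 islets, and of 19 of 23 genes of glucose sensing and the mature beta cell and 16 of 25 genes of insulin granule exocytosis. Levels were lower for 6 of 13 fetal growth genes, 21 of 25 fibroblast genes and 5 of 9 duct genes. As sets, the lists of cell division, DNA replication, genes that mature beta cells keep low and endothelium were also lower, calls that were lost when the correlation between genes was estimated (adjusted p = 0.107, 0.0584, 0.0970 and 0.313 with an estimated correlation). Of 10124 genes tested, 1265 were higher and 1394 lower in adult islets at a false discovery rate (FDR) under 0.05 in edgeR's quasi-likelihood test, and 7465 did not pass. Large changes were mostly falls, with 173 genes at least 8-fold lower and 21 at least 8-fold higher. Among genes changed at least 2-fold, 912 fell and 433 rose. The 2 groups did not overlap in 2615 of the 2659 genes called. Over all tested genes they did not overlap in 42.3%, where chance gives 10%. Directions depend on the scaling, and the insulin share, which differed between the ages, was not tested alone as the reason. With library totals alone, without composition factors, 343 genes were higher and 3612 lower, so that 8.67% of the calls were rises against 47.6%, and the median log2 fold change of all genes shifted by -0.49. All changes are therefore relative to the bulk of the genes.

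**Figure D1:**
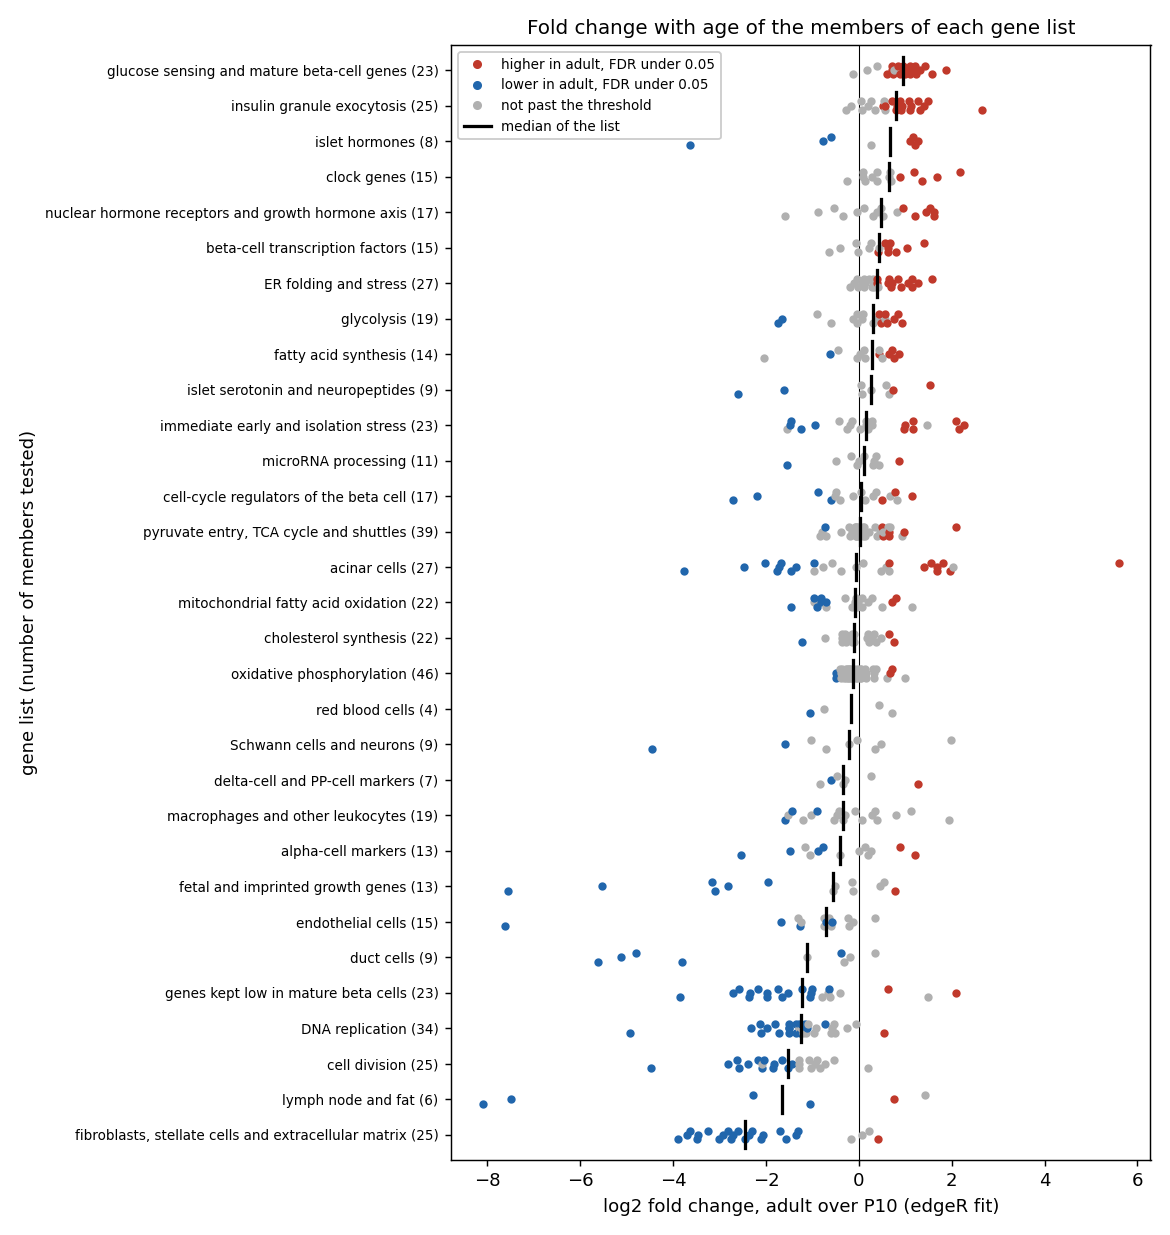
Each point is a tested gene, placed by its log2 fold change (adult over P10, edgeR) on the horizontal axis and by its gene list on the vertical axis, with the number tested in parentheses. Red and blue mark genes higher and lower in adult islets at an FDR under 0.05, grey those not past it, and black bars the list medians, which run from 0.95 for mature beta-cell genes to -2.46 for fibroblast and matrix genes. Under library totals alone every median would lie lower by about the shift of -0.49 given in the text, which leaves above 0 only those of mature beta-cell genes, exocytosis, islet hormones and clock genes.

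Of the 8 largest rises by fitted fold among genes averaging at least 5 CPM, with no overlap between the groups, the first was that of Pnlip, pancreatic lipase. It rose 48.4-fold, from 1.07 ± 0.134 to 50.9 ± 36.2 CPM (SD, n = 3), or 28.1-fold without adult replicate 3. Fga, a fibrinogen chain with a fitted fold of 41.6, had 125 counts in adults against 4 at P10. That is a ratio of normalised counts of 51.5 with a 95% counting interval of 19.6 to 191.8. Without P10 replicate 4, 1 count was left at P10 and the ratio was 159.9 (28.2 to 6367), and without P10 replicate 1 it was 30.8 (11.7 to 114.9). Hpx, the haem-binding plasma protein hemopexin, rose 39.7-fold to 111 ± 27.8 CPM (SD, n = 3). Ifit3 and Rsad2, both induced by interferon, rose 18.5-fold and 13.6-fold. The Rsad2 fold was 8.19 without adult replicate 3 and 21.5 without P10 replicate 1. Cck, cholecystokinin, rose 15.7-fold, Serpina6, the corticosteroid-binding globulin, 14.4-fold, and Nptx1, neuronal pentraxin, 13.8-fold. Without P10 replicate 1, which had no counts of these 3 genes, they rose 9.99-fold, 9.23-fold and 8.74-fold. Without P10 replicate 3, 5 counts of Nptx1 were left at P10 and its ratio was 38.8 (16.3 to 120.9). The 8 log2 fold changes ran from 3.77 ± 0.46 (SE) for Rsad2 to 5.60 ± 0.49 for Pnlip, with edgeR FDRs from 1.31e-09 for Hpx to 0.00254 for Serpina6.

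The 8 largest falls under the same criteria were those of H19, Spp1, Dlk1, Krt17, Prss22, RGD1359290, Cldn5 and Cthrc1. H19, an imprinted non-coding RNA abundant before birth, fell 189-fold, from 276 ± 36.5 to 1.34 ± 0.859 CPM (SD, n = 3). Spp1, the duct protein osteopontin, fell 49.3-fold from 706 ± 34.5 CPM, Dlk1, an imprinted inhibitor of differentiation, 46.2-fold, and Krt17, a keratin, 43.8-fold. The protease gene Prss22 had 484 counts against 5, a ratio of 58.8 (95% counting interval 25.02 to 181.9). All 5 lay in adult replicate 1, without which the gene was at least 72.2-fold lower, and without adult replicate 3 the ratio was 29.7 (12.7 to 91.99). RGD1359290 had 248 counts at P10 and none in adults, so it was at least 50.2-fold lower, set against 3 counts over the adult group. Cldn5, a tight junction gene of endothelium, had 423 counts against 1, a ratio of normalised counts of 257 with a 95% counting interval of 45.9 to 10170. That count lay in adult replicate 3, without which the gene was at least 43.3-fold lower. Cthrc1 had 458 counts against 2, a ratio of 139 with an interval of 38.3 to 1152, and of 70.3 (19.4 to 582.6) without adult replicate 3.

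Among the islet hormones, 4 of 8 rose and 3 fell (adjusted over the list alone, 5 and 3). Ins1 and Ins2, the rat insulin genes, rose 2.13-fold and 2.25-fold. Iapp, islet amyloid polypeptide, rose 2.32-fold, and Ppy, pancreatic polypeptide, 2.41-fold. Gcg, glucagon, fell 1.71-fold, from 25584 ± 1668 to 14983 ± 2322 CPM (SD, n = 3). Pyy, peptide YY, fell 1.52-fold, and Ghrl, ghrelin, fell 12.5-fold from 127 ± 13.9 to 10.1 ± 2.64 CPM (SD, n = 3). Sst, somatostatin, had a log2 fold change of 0.26 ± 0.12 (SE) and did not pass (edgeR FDR = 0.128), except without P10 replicate 4 (FDR = 0.0344, the lowest over the alternatives, whose highest was 1.00). Its sign turned under library totals alone (-0.23). Because Ins1 and Ins2 are near-identical in their coding parts and only unique alignments were counted, the division of reads between them is uncertain.

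Genes of glucose sensing and of the mature beta cell rose together: 19 of 23 rose (adjusted over the list alone, 20) and the other 4 did not pass, among them Ffar1 and Slc30a8, named for their number. Slc2a2, the glucose transporter GLUT2, rose 2.34-fold, and Ucn3, urocortin 3, a marker of mature beta cells, 2.02-fold. Ptprn, a granule membrane protein, rose 3.70-fold to 1846 ± 133 CPM (SD, n = 3), and Pcsk1, a proinsulin convertase, 2.68-fold. As a set the list was higher in adults (limma camera, adjusted p = 1.65e-17), also with an estimated correlation (adjusted p = 0.0333 with an estimated correlation). With library totals alone 12 members were higher and 1 lower. Fibroblast and duct genes were lower in the same libraries, with median log2 fold changes of -2.46 and -1.12.

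Of the insulin granule exocytosis genes, 16 of 25 rose (adjusted over the list alone, 19) and 9 did not pass. Syt4, a synaptotagmin, rose 6.28-fold, from 31.8 ± 5.25 to 198 ± 29.4 CPM (SD, n = 3). The set was higher (camera, adjusted p = 5.40e-12; adjusted p = 0.0299 with an estimated correlation). Library totals alone gave 9 exocytosis genes higher and 3 lower. In the same libraries genes of all endocrine cells, a list chosen after the data were seen, had a median log2 fold change of 0.48. Those of fibroblasts and ducts had medians of -2.46 and -1.12. Of the beta-cell transcription factors, 8 of 15 rose (adjusted over the list alone, 8), among them Nkx6-1, which rose 2.04-fold, and Foxo1, which rose 2.64-fold. Pdx1 did not pass, at 129 ± 5.12 and 150 ± 5.42 CPM (SD, n = 3; edgeR FDR = 0.213), and its sign turned under library totals alone (-0.27). The transcription factor set was higher (camera, adjusted p = 0.00832) but not with the correlation estimated from the data (adjusted p = 0.276 with an estimated correlation) nor with library totals alone, where 2 rose and 4 fell (adjusted p = 0.123, over a range of 0.00302 to 0.276 across the alternatives). Without adult replicate 1, 4 of these factors passed. Mafa was not analysed here.

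Alpha-cell markers went both ways, with 2 of 13 higher and 4 lower (adjusted over the list alone, 2 and 5). Gcg was among the lower ones, and the amino acid transporter Slc38a5 rose 2.31-fold. Among the delta-cell and PP-cell markers Ppy was the 1 riser and Pyy the 1 faller of 7, counts that were the same when adjusted over the list alone. Neither set was called (camera, adjusted p = 0.601 and 0.857). Under library totals alone 1 alpha-cell marker was higher and 8 were lower, and 1 delta-cell or PP-cell marker was higher and 5 were lower.

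**Figure D2:**
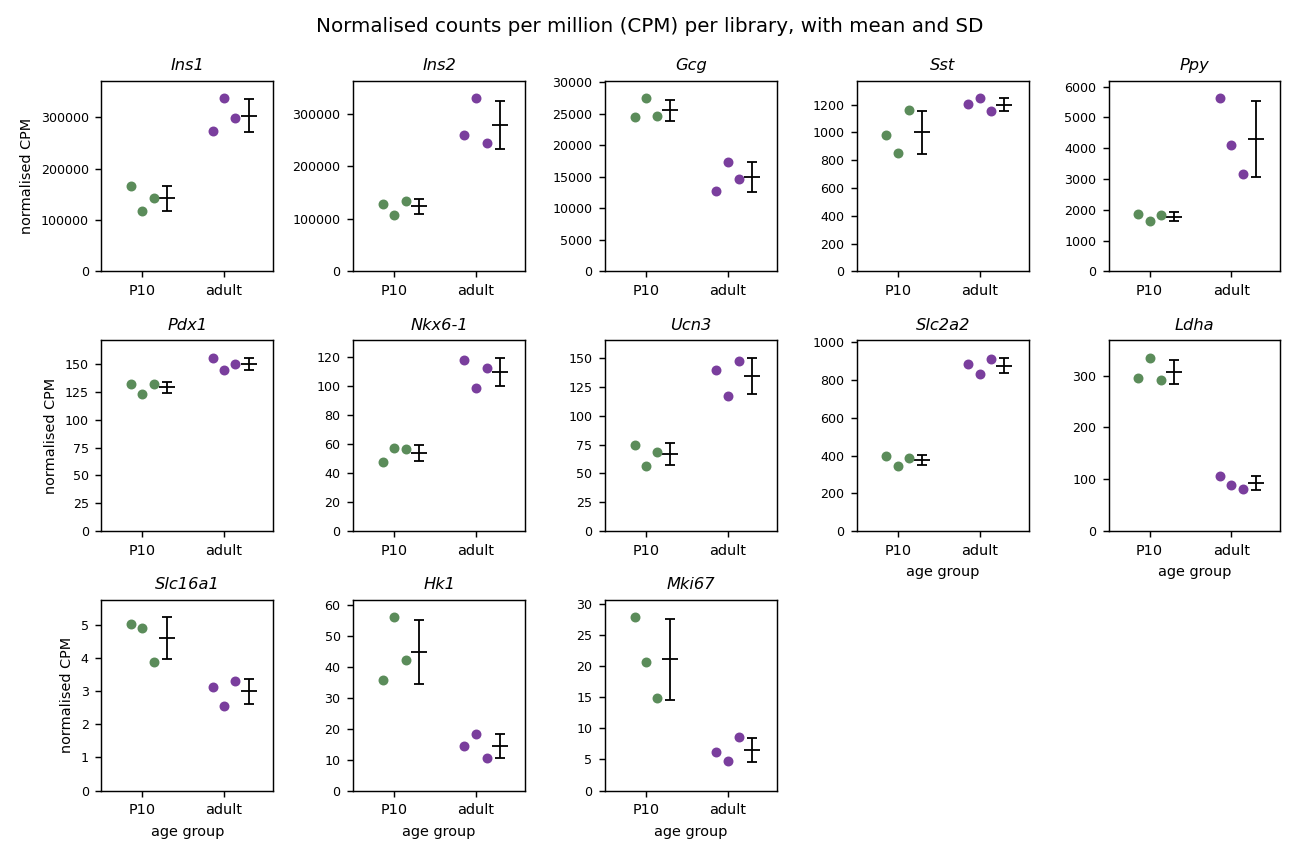
The 13 panels show genes named whatever their result, with normalised CPM on a linear vertical axis from 0 and the age groups on the horizontal axis. Coloured points are single libraries, 3 per group, and black marks give the mean with the SD. Slc2a2 lies at 375 ± 27.5 CPM at P10 and 877 ± 41.1 CPM in adults, and Ldha at 307 ± 23.6 and 92.3 ± 13.6 CPM.

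Genes that mature beta cells keep low were mostly lower in adult islets: 16 of 23 fell and 2 rose (adjusted over the list alone, 17 and 3). Ldha, lactate dehydrogenase A, fell 3.34-fold, Hk1, the low-Km hexokinase, 3.14-fold, and Tgm2, transglutaminase 2, 5.95-fold. Slc16a1, the monocarboxylate transporter MCT1, was low at both ages, at 4.60 ± 0.624 and 2.99 ± 0.384 CPM (SD, n = 3), and did not pass (edgeR FDR = 0.472). Ndrg4 went the other way and rose 4.28-fold. The set was lower (camera, adjusted p = 8.76e-07), a call lost when the correlation was estimated (adjusted p = 0.0970 with an estimated correlation). Several members, such as Pdgfra and Cxcl12, named after their values were seen, are also expressed by fibroblasts, whose genes fell in the same libraries by a median log2 fold change of -2.46.

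In the cell division list 13 of 25 genes fell (adjusted over the list alone, 14), with Top2a, a topoisomerase of dividing cells, 4.12-fold lower, Cdk1 3.56-fold lower and Mki67, the Ki-67 antigen, 3.15-fold lower. Mki67 went from 21.1 ± 6.51 to 6.54 ± 1.95 CPM (SD, n = 3; edgeR FDR = 0.00224). In the DNA replication list 20 of 34 fell (adjusted over the list alone, 23), including the helicase subunits Mcm2, 2.82-fold, and Mcm3, 4.28-fold. Gins2 was the exception and rose 1.45-fold, though not past the threshold under library totals alone (log2 fold change 0.04). Both sets were lower (camera, adjusted p = 2.26e-05 for division and 3.25e-07 for replication), and neither call held with the correlation estimated (adjusted p = 0.107 and 0.0584 with an estimated correlation). In the same libraries genes of fibroblasts, ducts and endothelium were lower too, with median log2 fold changes of -2.46, -1.12 and -0.72, and the cells that held the proliferation genes were not identified.

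Of the cell-cycle regulators, 3 of 17 rose and 4 fell (adjusted over the list alone, 3 and 4). Ccnd1, cyclin D1, rose 2.20-fold, Cdk4, its kinase partner, fell 1.84-fold, and Cdkn1c, the imprinted inhibitor p57, fell 6.50-fold from 5.31 ± 2.00 CPM (SD, n = 3). The Cdkn1c call was lost without P10 replicate 1 or 4 or adult replicate 1 or 2 (edgeR FDR from 0.0552 to 0.104), and without adult replicate 3 a single adult count was left (ratio 31.3, interval 5.50 to 1249.6). Without any 1 of the 6 libraries, between 1 and 3 members of the list rose and between 1 and 3 fell. It was 1 higher and 6 lower under library totals alone.

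Of the fetal and imprinted growth genes, 6 of 13 fell and 1 rose, both over all genes and adjusted over the list alone. H19 and Dlk1 fell most clearly, whereas Igf2, named outside the rule, did not pass (log2 fold change -0.16, edgeR FDR = 0.468). Plagl1, an imprinted zinc finger gene, rose 1.71-fold. That rise was lost without P10 replicate 3, adult replicate 1 or adult replicate 3 (edgeR FDR from 0.0825 to 0.0971). The set was lower (camera, adjusted p = 3.39e-08; adjusted p = 0.0333 with an estimated correlation). In the same libraries fibroblast and duct genes were lower, with median log2 fold changes of -2.46 and -1.12.

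In glycolysis 7 of 19 rose and 2 fell (same when adjusted over the list alone), with Aldoa, an aldolase, 1.68-fold and Pfkfb2, a phosphofructokinase regulator, 1.78-fold higher, and Ldha and Hk1 lower. Among the genes of pyruvate entry, the tricarboxylic acid (TCA) cycle and shuttles, 6 of 39 rose and 1 fell (adjusted over the list alone, 5 and 1). Pc, pyruvate carboxylase, rose 4.26-fold from 46.8 ± 8.64 to 199 ± 8.62 CPM (SD, n = 3), Mdh1, cytosolic malate dehydrogenase, rose 1.97-fold, and Mpc1, a pyruvate carrier subunit, fell 1.66-fold. In oxidative phosphorylation 2 of 46 rose, Atp5g1 (1.59-fold) and Cox8a (1.64-fold), and 2 fell, one of them Atp5c1 (1.41-fold); adjusted over the list alone, 2 and 1 passed. Under library totals alone no glycolysis gene was higher and 8 were lower, 2 TCA cycle and shuttle genes were higher and 13 lower, and 35 oxidative phosphorylation genes were lower. None of these sets was called (camera, adjusted p = 0.453, 0.113 and 0.743), except oxidative phosphorylation as lower under library totals alone (adjusted p = 0.0481, with others up to 0.991) and the TCA cycle set as higher without adult replicate 3 (adjusted p = 0.0366, with others up to 0.507).

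In mitochondrial fatty acid oxidation 6 of 22 fell and 2 rose (adjusted over the list alone, 7 and 2). Acaa2, a thiolase, fell 2.74-fold and Etfb, an electron transfer flavoprotein subunit, 1.75-fold, while Hadh, a beta-oxidation enzyme abundant in beta cells, rose 1.73-fold. In fatty acid synthesis 5 of 14 rose and 1 fell (same when adjusted over the list alone), with Scd, stearoyl-CoA desaturase, 1.81-fold and Acly, ATP citrate lyase, 1.70-fold higher. Without adult replicate 1 or adult replicate 2, 3 and 2 of them rose. Acaca, acetyl-CoA carboxylase, fell 1.54-fold, a call lost without any 1 of the 6 libraries (edgeR FDR from 0.0761 to 0.152). In cholesterol synthesis 2 of 22 rose and 1 fell (same when adjusted over the list alone). Insig1 rose 1.70-fold, Lss, lanosterol synthase, 1.57-fold, and Pmvk fell 2.32-fold, and between 1 and 4 genes of the list rose when single libraries were left out. The Lss call was lost without P10 replicate 3, adult replicate 1 or adult replicate 2 (edgeR FDR from 0.0587 to 0.0683). These sets were not called (camera, adjusted p = 0.451, 0.190 and 0.857). With library totals alone no gene of fatty acid oxidation was higher and 13 were lower, 1 gene of fatty acid synthesis was higher and 4 were lower, and no cholesterol gene was higher and 9 were lower.

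Genes of endoplasmic reticulum (ER) folding and stress rose in 13 of 27 cases (adjusted over the list alone, 14) and the rest did not pass. Ero1lb, a beta-cell oxidase for disulphide formation, rose 3.00-fold, and Atf6, a sensor of unfolded proteins, 2.21-fold. The set was higher (camera, adjusted p = 4.09e-05), not with the correlation estimated (adjusted p = 0.201 with an estimated correlation), and under library totals alone 3 members were higher and 4 lower. Of the immediate early and isolation stress genes 7 of 23 rose and 4 fell, also when adjusted over the list alone, whereas 4 were higher and 9 lower under library totals alone. Hmox1, haem oxygenase, rose 4.24-fold, Fos rose 4.45-fold to 88.1 ± 47.4 CPM (SD, n = 3), and Ier3 fell 1.94-fold. That set was not called (camera, adjusted p = 0.205).

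Of the nuclear hormone receptors and growth hormone axis genes 6 of 17 rose, also when adjusted over the list alone, and the others did not pass. Igf1r, the IGF-1 receptor, rose 3.09-fold and Vdr, the vitamin D receptor, 3.06-fold. The set was higher (camera, adjusted p = 0.00940), but not with the correlation estimated (adjusted p = 0.313 with an estimated correlation) or without adult replicate 1 (adjusted p = 0.0926, over a range of 0.00370 to 0.313 across the alternatives). With library totals alone 4 members were higher and 3 lower. Of the clock genes 5 of 15 rose (adjusted over the list alone, 6), with the repressor Nr1d1 3.23-fold and the output gene Dbp 2.55-fold higher. The set was higher (camera, adjusted p = 0.00159; adjusted p = 0.118 with an estimated correlation). The labels give no hour of islet isolation.

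Among microRNA processing genes 1 of 11 rose and 1 fell, also when adjusted over the list alone. Prkra, a Dicer partner, fell 2.91-fold. Eif2c2, which encodes Argonaute 2, rose 1.81-fold, a call lost without P10 replicate 1 or any 1 adult library (edgeR FDR from 0.0510 to 0.0906). Among the serotonin and neuropeptide genes 2 of 9 rose and 2 fell (adjusted over the list alone, 3 and 2). Vgf, a granule peptide precursor, rose 2.89-fold, Penk, proenkephalin, fell 6.11-fold, and Ddc, which makes serotonin and dopamine, rose 1.68-fold, not past the threshold without P10 replicate 3, P10 replicate 4 or adult replicate 1 (edgeR FDR from 0.0546 to 0.0631). Neither set was called (camera, adjusted p = 0.678 and 0.449). With library totals alone no microRNA processing gene was higher and 3 were lower, and 1 serotonin or neuropeptide gene was higher and 3 were lower.

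Markers of cells other than endocrine cells changed with age in the same libraries. Of the genes of fibroblasts, stellate cells and extracellular matrix 21 of 25 fell and 1 rose, also when adjusted over the list alone. Col1a1, a collagen I chain, fell 14.97-fold, from 1737 ± 196 to 117 ± 17.7 CPM (SD, n = 3), and Col3a1 fell 11.2-fold. Timp1, a protease inhibitor, rose 1.34-fold with overlapping groups. Its call was lost without P10 replicate 3, P10 replicate 4, adult replicate 2 or adult replicate 3 (edgeR FDR from 0.109 to 0.183), and its sign turned under library totals alone (-0.075). The set was lower (camera, adjusted p = 3.44e-42; adjusted p = 0.0333 with an estimated correlation).

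Of the duct genes 5 of 9 fell (adjusted over the list alone, 6) and none of the rest passed, with Spp1 and the keratin Krt19, 13.98-fold lower, the clearest (camera, adjusted p = 7.03e-12; adjusted p = 0.0299 with an estimated correlation). Of the endothelial genes 5 of 15 fell, also when adjusted over the list alone, among them Cldn5 and Egfl7, which fell 3.22-fold. The other 10 did not pass, among them Pecam1, Cdh5 and Kdr, named outside the rule (edgeR FDR = 0.626, 0.379 and 0.683). Without adult replicate 1, 3 endothelial genes passed. The genes lower with library totals alone were 8 of the duct list and 10 of the endothelial list. The endothelial set was lower (camera, adjusted p = 0.00682), but not with the correlation estimated (adjusted p = 0.313 with an estimated correlation).

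Acinar genes, which encode digestive enzymes, went both ways, with 8 of 27 higher and 9 lower (adjusted over the list alone, 9 and 9). Pnlip rose, whereas Reg1a, a secreted lectin, fell 13.5-fold and Clps, colipase, 4.05-fold. Adult replicate 3 held the most Pnlip, 92.7 CPM against 30.4 and 29.7 CPM in the other adult libraries. The acinar set was not called (camera, adjusted p = 0.486), but without adult replicate 3 it was lower, with 5 genes higher and 14 lower (adjusted p = 1.36e-09, with others up to 0.952).

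Of the leukocyte genes 3 of 19 fell (adjusted over the list alone, 2), including Coro1a, 3.00-fold, and Lyz2, 2.70-fold. Without P10 replicate 1, 4 leukocyte genes were higher and 2 lower; without P10 replicate 3, 1 was higher and 5 lower; and without adult replicate 2, 1 was higher and 1 lower. Coro1a kept its call whichever library was left out, and Lyz2 lost it without adult replicate 2 (edgeR FDR = 0.05002, over a range of 0.000645 to 0.0946 across the alternatives). The leukocyte set was not called (camera, adjusted p = 0.486). In the list of Schwann cells and neurons 2 of 9 fell, also when adjusted over the list alone, S100b and Ngfr (2.99-fold; camera for the set, adjusted p = 0.555). S100b had 213 counts against 5, a ratio of 25.9 with a 95% counting interval of 10.9 to 80.5. Of the lymph node and fat genes 4 of 6 fell and 1 rose (adjusted over the list alone, 4 and 2), with Fabp4 4.83-fold and Lpl 2.07-fold lower (camera, adjusted p = 0.0948). The other members that fell were the lymph node chemokine genes Ccl21 and Ccl19, named outside the rule (edgeR FDR = 0.00179 and 0.00188). Cidec rose 1.70-fold, a call lost without P10 replicate 3, P10 replicate 4, adult replicate 1 or adult replicate 3 (edgeR FDR from 0.0856 to 0.152). Of 4 red blood cell genes tested, Hbb, a beta globin, fell 2.09-fold; adjusted over the list alone, 2 were lower and 1 higher. Library totals alone gave 7 leukocyte genes, 4 Schwann cell and neuron genes and 2 red blood cell genes lower. The globin copies are near-identical, so their reads are hard to divide.

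In all, camera called 6 lists as higher and 7 as lower among the 30 with at least 5 tested members, and 2 and 3 of these calls held with an estimated correlation. The median, mean and test of a list differed in sign for islet hormones (median 0.68, mean -0.00, test up), cell-cycle regulators (0.04, -0.19, up), cholesterol synthesis (-0.11, -0.05, up), serotonin and neuropeptides (0.26, -0.04, up) and acinar genes (-0.06, 0.01, down). Libraries of the same group differed by more than counting noise in every pair, with a chi-square per degree of freedom between 6.13 and 17.3, so none was counted as a duplicate. The first principal component of log2 CPM held 59.2% of the variance and separated the ages. On the second, with 14.8%, P10 replicate 1 lay at 42.2 and the other P10 libraries at -27.3 and -22.2. P10 replicate 1 had the most gene counts of its group but the fewest genes with a count, 11182 against 12062 and 12369. Its share of alignments that were not unique was the largest, 27.7%. On the third, with 12.2%, adult replicate 3 lay at -39.1 and the other adult libraries at 20.6 and 23.3. Adult replicate 3 also had the most gene counts of its group and the fewest genes with a count, 11342 against 11607 and 11638. Ribosomal RNA genes took 3.36% ± 1.74 of the counts at P10 and 4.44% ± 0.259 in adults (SD, n = 3; exact two-sided permutation p = 0.4). Age coincided with any difference in handling, and the sex of the pups was not among the labels used here.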

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

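The tests on lists of cell types and on acinar genes below, and the comparison of non-unique alignments, were chosen after the results were seen.

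Alignments that were not unique, which enter no gene count, made up 24.8% ± 2.47 (SD, n = 3) of gene counts and counters at P10 and 16.4% ± 1.35 (SD, n = 3) in adults. The item was picked out because these counters lie outside the counts compared. The exact permutation p was 0.1, the smallest possible here. Per 100 gene counts other than insulin there were 48.7 ± 8.07 at P10 and 38.3 ± 2.16 in adults (SD, n = 3).

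Genes of fibroblasts (21 of 25) and ducts (5 of 9) were lower and genes of mature beta cells (19 of 23) higher in adult islets. Dilution of all other cell types alike by endocrine cells, as the only source, would lower their genes alike. The median log2 fold change of fibroblast genes lay at -2.46 and that of leukocyte genes at -0.33. That is a difference of -2.13 (permutation p = 6.0e-04, across genes, which are not independent replicates). The difference argues against equal dilution as the only source. Equal dilution beside a change of expression within fibroblasts is not excluded, because list medians do not measure cell amounts. A larger share of endocrine cells as the only source would raise both kinds of endocrine genes alike. Genes of all endocrine cells had a median of 0.48 and the mature beta-cell genes one of 0.95. The difference was 0.47 (permutation p = 0.0051, across genes, which are not independent replicates). The mature beta-cell list, compared with all 23 members, also holds genes of other endocrine cells, such as Ptprn, Pcsk2 and Cpe. The difference therefore cannot tell beta cells from endocrine cells as a whole. The difference lay between 0.42 and 0.49 without single libraries, with a permutation p of 0.0552 at 0.43 without P10 replicate 1. The hormone genes went both ways: of 8, Gcg, Pyy and Ghrl fell, whereas Ins1, Ins2, Iapp and Ppy rose. A change of gene expression with age within beta cells, or a larger share of beta cells among endocrine cells, may contribute, and neither was tested.

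Acinar genes moved in both directions, whereas more or less acinar tissue carried over would, on its own, move them one way, and 8 passed on the smaller side. Adult replicate 3, the library with the most Pnlip, is not the whole source, since 5 of those 8 genes were also called higher without it. It also held 2219 Cpa1 counts against 253 and 317 in adult replicates 1 and 2, and 2634 Amy2a3 counts against 393 and 322. That library also had 6280144 gene counts in all against 3307415 and 3481376, so these raw counts overstate its excess. Without it the acinar set was called lower, as given above. A different amount of acinar tissue beside a changed mix is therefore not excluded. Reads shared between paralogous enzyme genes stay open: of members with no close paralog in the list 3 rose and 4 fell, but without adult replicate 3 it was 1 and 5. Within each library, the log2 ratio of Pnlip to Cpa1 counts, with 0.5 added to each, was -8.84 ± 0.30 at P10 and -1.87 ± 0.32 in adults (SD, n = 3; exact permutation p = 0.1, the smallest possible). These genes were picked for their changes, so the ratio restates the pattern, and a switch of the enzyme mix with age stays open.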

How the results depend on the processing

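The alternatives were fixed before the data were examined, except leaving out ribosomal RNA genes. No gene called in the main test was called in the opposite direction under any alternative run. With library totals alone 343 genes were higher and 3612 lower in adult islets, where the median of all genes moved by -0.49, and log2 fold changes turned sign for Sst (-0.23), Pdx1 (-0.27) and Timp1 (-0.075). Against a 1.5-fold change 337 were higher and 624 lower, as a stricter null hypothesis leaves fewer. With the replicate block 679 were higher and 729 lower. The replicate numbers are those of the sample titles, while the names of the deposited counts number the P10 libraries 1, 2 and 3. A block by those other numbers was not run. Whether the title numbers 1 and 3 stand for a shared day or batch is not given by the labels. Same-numbered libraries had correlations of deviations of -0.024 and -0.0049, which cannot show that nothing was shared. The title numbers 2 and 4 occur in a single group, so with the block the ages are compared only within title numbers 1 and 3. The block also costs degrees of freedom. With an estimated correlation 2 lists were higher and 3 lower, against 6 and 7; fry, which does not compare a list with other genes, gave 9 and 9. Leaving out 1 library left between 923 and 1262 genes higher and between 1040 and 1266 lower. The other alternatives (relative log expression factors, factors without hormone and acinar genes, DESeq2, both filters, no ribosomal RNA genes) gave between 1210 and 1386 genes higher and between 1373 and 1480 lower. Of 94 named genes 65 kept their direction and side of the threshold under every alternative. Calls were lost by 25 against a 1.5-fold change, 17 with the block and 14 with library totals alone. At these depths, of simulated 2-fold changes 15 of the 50 with lower expression and 39 of the 50 with higher expression were recovered.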

Other observations

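The gene lists and tests in this part, other than the planned comparison of all splits of the libraries, were chosen after the data were seen, and the genes named here were too.

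Interferon-stimulated genes were higher in adult islets, with 28 of 50 tested members higher and 2 lower and a median log2 fold change of 0.99 (camera, adjusted p = 8.82e-14 over 5 such lists; adjusted p = 0.155 with an estimated correlation). Without P10 replicate 1, which lay apart from the other P10 libraries on the second principal component, 37 were higher and 1 lower, with a median of 1.42. Usp18 and Isg15 had log2 fold changes of 2.80 ± 0.28 and 2.38 ± 0.24 (SE; edgeR). Irf7, a transcription factor of the antiviral response, stood at 22.8 ± 16.4 CPM at P10 and 167 ± 71.5 CPM in adults (SD, n = 3). The class I histocompatibility genes RT1-A2 and RT1-CE16, members of a near-identical family, had log2 fold changes of 2.07 and 3.54. Psmb10 and Ifitm3 went the other way. Acute-phase and NF-kB genes split, with 13 of 24 higher, such as Fgb, C3, Cxcl10 and Sod2, and 5 lower, such as Serpina3n and Cp (camera, adjusted p = 4.14e-08; adjusted p = 0.123 with an estimated correlation). Fgb, a fibrinogen chain, went from 90.7 ± 9.4 to 1038 ± 202 CPM (SD, n = 3).

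Genes of cytosolic ribosomal proteins were lower in adult islets, with 63 of 72 lower and a narrow spread around a median log2 fold change of -0.58 (quartiles -0.73 and -0.45; camera, adjusted p = 1.95e-17; adjusted p = 0.123 with an estimated correlation). Under library totals alone 71 were lower. Many have processed pseudogenes, so their unique counts are uncertain.

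More leukocytes in the adult preparations would be a possible explanation of the interferon-stimulated genes, but the leukocyte list had a lower median log2 fold change. It was -0.33 (95% bootstrap interval -0.89 to 0.28), below the 0.99 (0.70 to 1.47) of the interferon list. These intervals resample list members, not libraries, so they do not measure the spread between replicates. Without P10 replicate 1 the medians were 0.0070 (-0.46 to 0.73) and 1.42 (1.05 to 1.96). Scaling of libraries with different insulin shares is argued against as the whole source, since 21 of the 28 were also called higher with library totals alone, but 5 of the 50 were then lower and the median was 0.51, and the acute-phase list had 12 higher and 8 lower. Different handling, culture or housing of the 2 ages cannot be told apart from age, because each library of an age shares it. The isolation stress list (camera, adjusted p = 0.205) does not decide this. Age itself stays open as untested.

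Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many genes as the 2659 called. The highest of the others in edgeR was 0, where up to 211 genes had an unadjusted p under 0.05. Every other split mixed the ages in both of its groups, which widens the spread within them, so few calls could arise there whatever the source of the difference. With 10 splits a share under 0.05 cannot be reached.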
